A study of Homo sapiens with 37 samples.

How the data were processed

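Deposited raw counts (unit: count) of 19785 protein-coding genes were given for each time, per the submitters' processing notes from STAR 2.5.3 alignments to GRCh38. Deposited normalized values (unit: log2 CPM) were given for 11865 genes at 6 h and 12040 genes at 12 h. They equal voom values computed here from the raw counts with TMM factors, the largest absolute difference being 5.0e-06 and 5.0e-09. All 19785 gene identifiers matched the GENCODE annotation used for positions. T cell receptor genes were not analysed here, so the planned count of V genes per clone was not run.

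Library depth ran from 12.8 to 35.4 M counts at 6 h (median 19.9 M, 18 libraries) and from 10.6 to 48.4 M at 12 h (median 20.3 M, 19 libraries). Between 12591 and 13867 genes had a count at 6 h, and between 12889 and 14082 at 12 h. Among 68 pairs of libraries within a group, 0 were identical, and the smallest chi-square per degree of freedom was 21.3. One control library at 12 h has a genotype label that ends in K where the others end in NK, and it was kept as control.

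The comparisons, their settings and the gene lists were fixed before the data were examined. Genes were kept by filterByExpr over the 4 groups, counts were scaled by TMM, and each time was fitted on its own with 1 coefficient per group in edgeR 4.0.16 (R 4.3.3). The quasi-likelihood F-test was used, with p adjusted by Benjamini-Hochberg and 0.05 as the limit. AMTH17 was the mean of its 3 classes against control, and the trend gave control, Low, Medium and High equal steps. Time was tested over all 37 libraries with a coefficient per class and time. Standard errors were taken from the test as the fold change over the root of F. Other tools were DESeq2 1.42.0 and limma 3.58.1 (voom). Log2 CPM used a prior count of 2.

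Gene lists of at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes named with a change were the smallest p and the largest changes among called genes with an average log2 CPM of at least 1, members of the lists, and a fixed panel of effector genes. T cell receptor, immunoglobulin, HLA and Y-linked genes, XIST and TSIX were not named, as they may follow clone, donor or sex. They stayed in the counts of genes. At 12 h such genes made up 14 of the calls for High against control, 6 for High against Low and 11 for the trend. Results of 2 genes that these rules name are not reported here.

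Libraries of both times were paired by title number, with an offset of 25 between the times, a step chosen after the data were seen. Of 17 such pairs 16 were each other's best match over 11794 genes. The correlation of own pairs ran from 0.55 to 0.935 (median 0.845), against a median of 0.446 for the best other library. The class label differed within 4 of the pairs, and AMTH17 or control status in 0.

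A self-test drew counts from a negative binomial with the fitted means and dispersions and changed 50 genes at each fold. At 6 h 17, 38, 48 and 48 of 50 genes were found at 2-, 4-, 8- and 16-fold, with 4 false calls (2.58%). At 12 h it found 29, 44, 46 and 49, with 9 false calls (5.08%), and for time 36, 48, 50 and 50, with 8 false calls (4.17%). camera found a list of 20 genes raised 2-fold at each setting (adjusted p = 7.7e-17, 1.7e-31 and 2.4e-29) and called 0 of 100 unchanged lists. Each gene was drawn on its own, so the self-test holds no correlation between genes. It cannot tell how many false list calls such correlation gives at the preset value.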

Results

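Antimicrobial TH17 clones specific for Cutibacterium acnes (AMTH17) were compared with non-antimicrobial TH17 clones (n-AMTH17) after stimulation through CD3 and CD28. Polyadenylated RNA was sequenced at 6 h and at 12 h, and the AMTH17 clones carry a label of High, Medium or Low activity. The 37 libraries analysed comprised 14 AMTH17 and 4 n-AMTH17 libraries at 6 h, and 15 and 4 at 12 h. The labels do not tell which libraries come from which donor or clone, so the p-values measure the spread among libraries. Every change below is a log2 fold change ± standard error, with p adjusted by Benjamini-Hochberg over all genes tested.

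At 6 h AMTH17 clones carried more mRNA of HAVCR2, which encodes the inhibitory receptor TIM-3, and much less of the type 2 cytokine genes IL5 and IL9. HAVCR2 rose by 4.34 ± 0.76 (adjusted p = 0.0198; 14 AMTH17 and 4 n-AMTH17 libraries), PLEKHF1, which codes for an endosomal adaptor, by 1.63 ± 0.25 (adjusted p = 0.00701), and the TNF receptor gene TNFRSF1B by 1.01 ± 0.19 (adjusted p = 0.0388). IL5 fell by 9.10 ± 1.30 (adjusted p = 0.00427) and IL9 by 5.73 ± 0.87 (adjusted p = 0.00701). PLA2G4A and PTGS2, whose enzymes release arachidonic acid and turn it into prostaglandin, fell by 9.02 ± 1.03 (adjusted p = 0.00137) and 7.51 ± 0.92 (adjusted p = 0.00162). The adhesion genes CADM1 (−7.48 ± 1.05, adjusted p = 0.00427) and CDH1 (−5.67 ± 1.08, adjusted p = 0.0388) fell too, as did the mannosidase gene MAN1C1 (−6.92 ± 1.18, adjusted p = 0.016) and the heparanase gene HPSE (−4.12 ± 0.64, adjusted p = 0.00701). IL24 (−4.37 ± 0.60, adjusted p = 0.00427) and the IL-33 receptor gene IL1RL1 (−3.05 ± 0.55, adjusted p = 0.023) completed the cytokine and receptor genes that fell. In all, 3 genes were higher and 17 lower out of 11865 tested, with 1315 at unadjusted p under 0.05.

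The 6 h calls depended on the libraries tested. PLA2G4A and PTGS2 passed in each of the 18 fits that left out 1 library, whereas TNFRSF1B passed in 6 and CDH1 in 4. Even so, PLA2G4A ran from −3.45 to 6.75 log2 CPM in controls and from −3.45 to −0.15 in AMTH17 libraries at 6 h. Its fall therefore does not hold against every control. PTGS2 ran from 2.90 to 10.87 in controls and from 0.16 to 5.72 in AMTH17 libraries. At 12 h the ranges of PLA2G4A overlapped too (−2.55 to 6.77 and −3.43 to 0.29). Leaving out control replicate 1, 2 or 4 gave 11, 7 and 43 genes, and leaving out Low replicate 2 gave 39. Single control libraries carried much of some falls, as for CADM1 and IL24, and for IL9, HPSE and CDH1 mainly the call. Without control replicate 2 CADM1 was −2.23, MAN1C1 −4.54, IL5 −5.67, IL9 −4.74 and HPSE −3.37, without control replicate 1 IL24 was −1.75 and CDH1 −4.68, and none of these passed then. Within lane 2 alone PTGS2 was −7.53, PLA2G4A −9.43, IL5 −10.40 and HAVCR2 3.79, and none of the 4 passed there. With lane as a covariate PTGS2 (−8.17) and PLA2G4A (−9.39) passed, while HAVCR2 (3.69) did not.

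**Figure D1:**
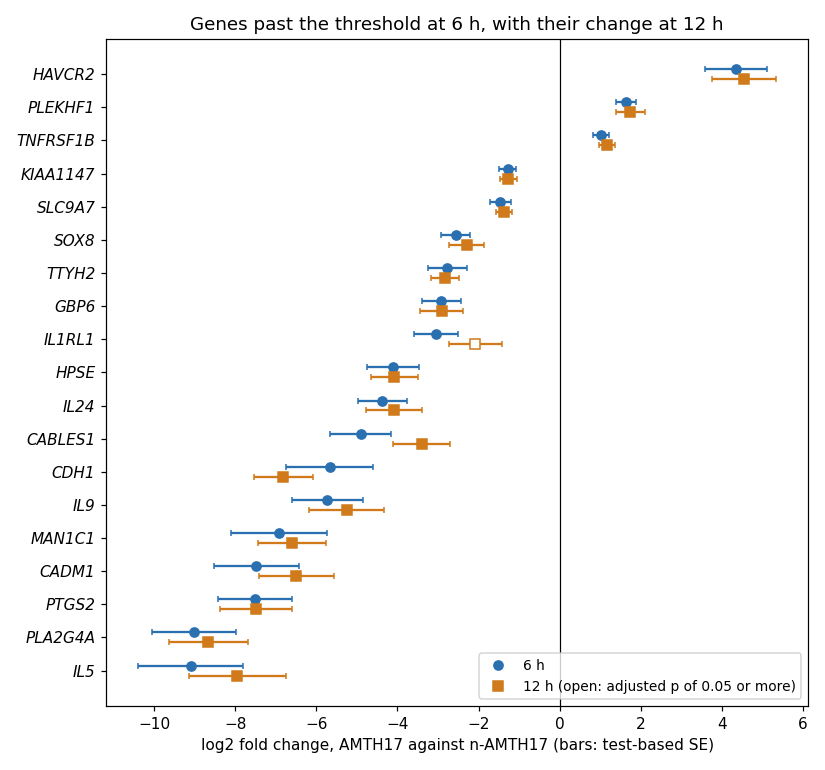
Log2 fold change of 19 genes that passed at 6 h, with their change at 12 h (bars, standard error). At 6 h HAVCR2 was higher by 4.34 and PLA2G4A lower by 9.02 in AMTH17 clones.

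At 12 h cytokine genes of the TH17 lineage passed, and IL17A and IL26 were higher in AMTH17 clones. IL17A rose by 8.50 ± 2.08 (adjusted p = 0.0362, 15 AMTH17 and 4 n-AMTH17 libraries), IL26 by 4.88 ± 1.17 (adjusted p = 0.0339), CCL20 by 4.58 ± 1.20 (adjusted p = 0.0438) and the granzyme gene GZMB by 3.05 ± 0.81 (adjusted p = 0.0445). IL17A averaged 8.07 log2 CPM in Low, 5.48 in Medium and 3.99 in High clones, against −0.58 in controls. CCL20 averaged 9.90 in Low and 10.55 in Medium clones. In High clones it averaged 5.26 ± 4.00 (SD), near the 4.46 of controls. IL26 was alike in Low, Medium and High clones (2.56, 2.94 and 2.40), whereas GZMB was highest in High clones (11.99). Other genes that rose coded for the calcium-sensing receptor (CASR, 7.35 ± 1.87, adjusted p = 0.0401), collagens (COL5A3, 6.45 ± 1.38, adjusted p = 0.0223) and a serine protease (TMPRSS6, 5.02 ± 1.18, adjusted p = 0.031). The genes lowered at 6 h stayed low: PLA2G4A fell by 8.66 ± 0.97 (adjusted p = 0.000294), IL5 by 7.95 ± 1.20 (adjusted p = 0.00326), PTGS2 by 7.49 ± 0.88 (adjusted p = 0.000419) and CDH1 by 6.81 ± 0.73 (adjusted p = 0.000294). MAOA (−6.05 ± 1.28, adjusted p = 0.0214), ADCY1 (−5.67 ± 0.99, adjusted p = 0.0066) and the RANKL gene TNFSF11 (−5.48 ± 0.71, adjusted p = 0.000822) joined them. The first 2 rest on 1 control library: without control replicate 2 MAOA was 2.09 and ADCY1 −2.00, and neither passed. In all 234 genes rose and 254 fell out of 12040, with 3144 at unadjusted p under 0.05.

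At 12 h lane and class overlapped, as all 5 High libraries and 1 Low library ran in lane 3 and no control library did. Within lane 4 alone, with 4 control, 3 Low and 4 Medium libraries, 103 genes passed and 69 of them were among the 488 of the pooled fit. There IL17A (8.09), IL26 (4.62), CCL20 (5.77), IL5 (−9.25) and PTGS2 (−7.09) passed. GZMB, at 1.58, and HAVCR2, at 3.35, did not pass within that lane. With lane as a covariate 0 genes passed by edgeR (976 at unadjusted p under 0.05), with PTGS2 at −6.48. IL17A passed in 15 of the 19 fits that left out 1 library, and GZMB and CCL20 in 7. The count itself ran from 58 genes without control replicate 1 to 1075 without Low replicate 1, and was 984 without Low replicate 4. It fell to 83 or 258 without control replicate 3 or 4, 254 without Low replicate 2, 217, 245 or 312 without Medium replicate 1, 2 or 5, and 259 or 234 without High replicate 1 or 5.

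The change carried over between the times gene by gene. Of the 3 genes raised at 6 h all 3 were called higher at 12 h (expected 0.0595 if independent), and of the 17 lowered 16 were called lower (expected 0.359). The exception was IL1RL1, at −2.08 (adjusted p = 0.0702) at 12 h. Both times used the same clones, so these overlaps are not independent evidence.

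TH17 genes as a list rose and TH2 genes fell at both times. At 6 h, 0 of 21 TH17 genes passed across all genes and 12 rose when adjusted over the list alone, with a median change of 2.90 (camera, adjusted p = 1.0e-10, preset correlation, adjusted p = 0.24 with an estimated correlation). At 12 h, 7 of 22 rose, among them IL17A, IL26 and CCL20, 1 fell (IRF4) and 14 did not pass; 14 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 2.9e-07, adjusted p = 0.33 with an estimated correlation). Of 11 TH2 genes at 6 h, 3 fell (IL5, IL9 and IL1RL1) and 8 did not pass; 7 fell when adjusted over the list alone (camera, adjusted p = 1.8e-11, adjusted p = 0.032 with an estimated correlation). Of 10 at 12 h, IL5, IL9, IL4 (−4.28), GATA3 (−2.23) and IL17RB (−3.26) fell and 5 did not pass; 7 fell when adjusted over the list alone (camera, adjusted p = 2.9e-07, adjusted p = 0.076 with an estimated correlation). With lane as a covariate both lists had a camera call in the same direction at both times. By fry the TH2 list passed at 6 h (adjusted p = 0.012) and 12 h (adjusted p = 0.0012). The TH17 list passed by fry at 12 h (adjusted p = 0.031) and not at 6 h (adjusted p = 0.093).

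Genes of the cytotoxic granule leaned upwards in AMTH17 clones. At 12 h 3 of 17 rose, GZMB, GZMH (2.86) and CTSC (1.04), 14 did not pass, and 5 rose when adjusted over the list alone (camera, adjusted p = 0.0022, adjusted p = 0.33 with an estimated correlation). At 6 h 0 of 17 passed (camera, adjusted p = 5.3e-04, adjusted p = 0.24 with an estimated correlation). By fry the list passed at 12 h (adjusted p = 0.032) and not at 6 h (adjusted p = 0.093). Of 9 genes of secreted antimicrobial proteins at 12 h, IL26 and CCL20 rose while CXCL10 (−3.17), CXCL11 (−2.96) and CXCL9 (−2.77) fell, so the list had no direction (camera, adjusted p = 0.88). The interferon-induced genes OAS1, OAS2 and OAS3 fell at 12 h, as 3 of 29 members of the interferon list (camera, adjusted p = 0.27). Without control replicate 2 none of the 3 passed, and OAS1 (0.45) and OAS3 (0.35) turned in sign. Markers of other lymphocytes moved up with the granule genes. The unconventional T cell markers had medians of 2.36 at 6 h (camera, adjusted p = 0.00948, adjusted p = 0.30 with an estimated correlation) and 2.84 at 12 h (camera, adjusted p = 0.00685, adjusted p = 0.33 with an estimated correlation), with 0 of 6 genes passing at either time. By fry this unconventional T cell list passed at 12 h (adjusted p = 0.043) and not at 6 h (adjusted p = 0.15). Of 3 NK cell markers 2 rose at each time when adjusted over the list alone.

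Transcripts of replication-dependent histones, most of which lack a poly(A) tail, were higher as a list in AMTH17 clones at 6 h. None of 25 passed across all genes and 4 rose when adjusted over the list alone, with a median of 1.51 (camera, adjusted p = 1.8e-09, adjusted p = 0.24 with an estimated correlation). At 12 h 0 of 17 passed (camera, adjusted p = 0.005, adjusted p = 0.52 with an estimated correlation). Mitochondrial transcripts leaned up too, with a median of 0.33 at 6 h (camera, adjusted p = 0.0258, adjusted p = 0.59 with an estimated correlation) and 0.32 at 12 h (camera, adjusted p = 0.00933, adjusted p = 0.61 with an estimated correlation). Glycolysis genes leaned up at 6 h (camera, adjusted p = 0.0127, adjusted p = 0.30 with an estimated correlation) and at 12 h (camera, adjusted p = 0.00346, adjusted p = 0.61 with an estimated correlation), where lane as a covariate turned the list down without a call. Ribosomal protein genes leaned down, with a median of −0.12 at 6 h (camera, adjusted p = 0.00398, adjusted p = 0.67 with an estimated correlation) and −0.19 at 12 h (camera, adjusted p = 7.1e-04, adjusted p = 0.70 with an estimated correlation). The cholesterol synthesis genes also leaned down at 6 h (camera, adjusted p = 0.0146, adjusted p = 0.59 with an estimated correlation) and 12 h (camera, adjusted p = 0.00933, adjusted p = 0.61 with an estimated correlation). Proliferation genes leaned down at 6 h (camera, adjusted p = 0.00739, adjusted p = 0.59 with an estimated correlation) and had no call at 12 h (adjusted p = 0.40). By fry none of the lists named so far in this paragraph passed at either time, the smallest being adjusted p = 0.082 (histones, 12 h). The TH1 (0.22 and 0.36), Treg (0.34 and 0.051), Tfh (0.22 and 0.53), T cell activation (0.25 and 0.37) and extracellular trap (0.69 and 0.65) lists had no camera call at 6 h or 12 h, the values being adjusted p.

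The spread of the effector genes among AMTH17 clones was wide. IL17A averaged 5.84 ± 4.27 log2 CPM (SD, n = 14) at 6 h against −0.85 ± 0.18 in controls (n = 4), and its change of 10.10 did not pass (adjusted p = 0.231). IL22 did not pass at 6 h (8.08, adjusted p = 0.288) or 12 h (8.33, adjusted p = 0.0617), nor did IL17F (7.65, adjusted p = 0.292, and 7.60, adjusted p = 0.0654). The TH1 genes TBX21 (0.48, adjusted p = 0.777) and IFNG (2.13, adjusted p = 0.654) did not pass at 6 h, and IFNG (1.42, adjusted p = 0.514) did not at 12 h. GNLY, which codes for granulysin, did not pass across all AMTH17 clones (2.68, adjusted p = 0.345 at 6 h and 3.51, adjusted p = 0.0784 at 12 h) and separated by class: at 12 h it averaged 8.84 ± 1.33 log2 CPM in High (n = 5), 8.39 ± 0.93 in Medium (n = 5), 3.68 ± 1.80 in Low (n = 5) and 1.85 ± 2.93 in control clones (n = 4).

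**Figure D2:**
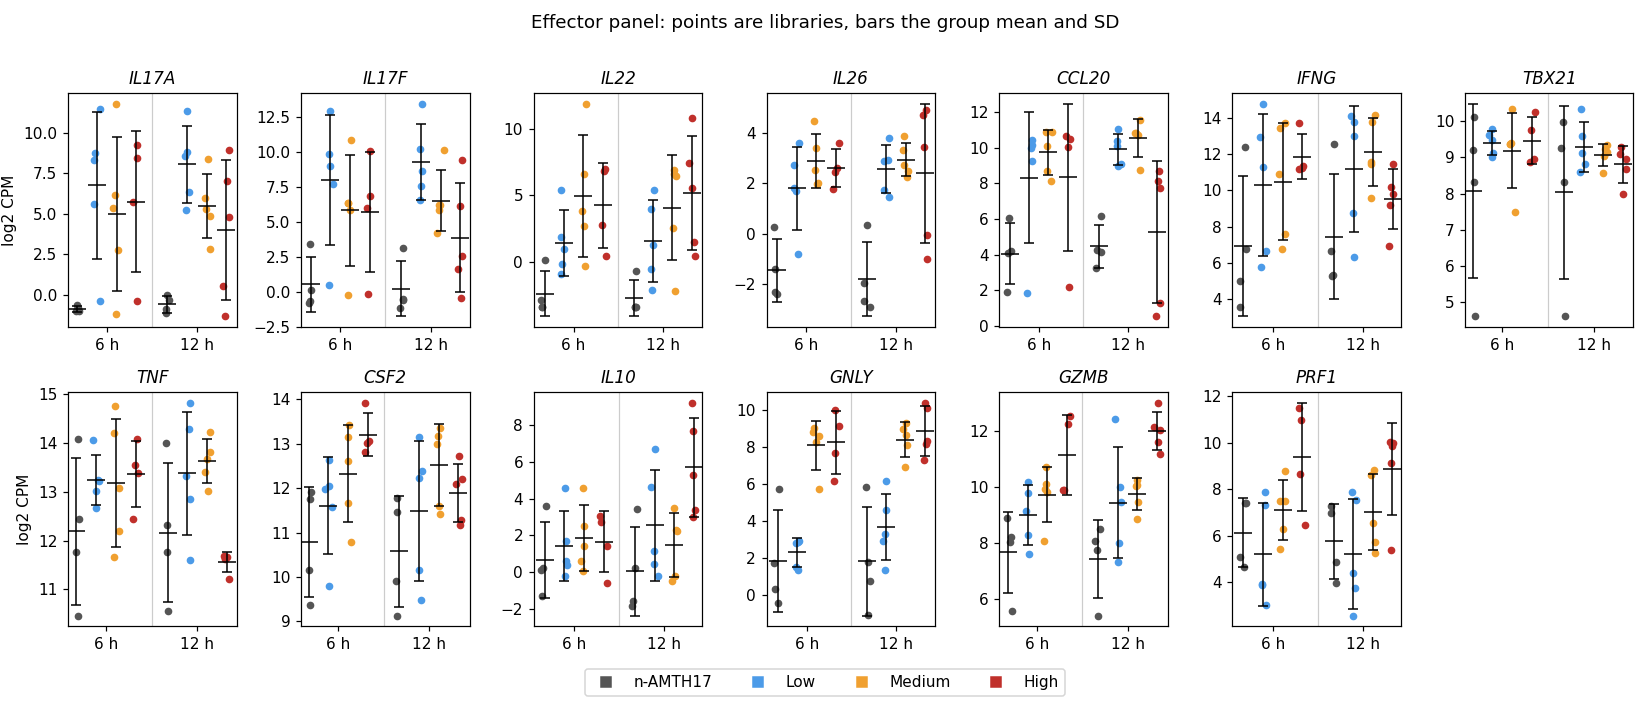
Log2 CPM of the effector gene panel by activity class at both times. GNLY at 12 h averaged 8.84 in High and 3.68 in Low clones.

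High clones at 12 h differed from controls in cytokine and cytotoxic effector genes among many others. IL22 rose by 10.93 (adjusted p = 0.0062; 5 High and 4 control libraries), GNLY by 5.34 (adjusted p = 0.00562), IL10 by 5.76 (adjusted p = 0.0207), GZMB by 4.33 (adjusted p = 0.00249) and PRF1 by 3.13 (adjusted p = 0.0438). SERPINB2, which codes for a plasminogen activator inhibitor, fell by 9.69 (adjusted p = 0.000816) and PTGS2 by 8.23. In all 2088 genes rose and 2527 fell; all 5 High libraries ran in lane 3, and with lane as a covariate 0 genes passed (391 at unadjusted p under 0.05). At 6 h only HAVCR2 (6.00, adjusted p = 0.0336) and PLEKHF1 (1.84, adjusted p = 0.0493) passed, with 1533 genes at unadjusted p under 0.05; limma-voom called 0 and DESeq2 315, and edgeR called 0 to 7 when 1 library was left out.

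Medium and Low clones at 12 h differed from controls by fewer genes. Medium clones had more HPGD (5.91, adjusted p = 0.019), which codes for a prostaglandin-degrading enzyme, and less PLA2G4A (−8.04) and CADM1 (−7.50), as 34 genes rose and 21 fell. Low clones had more HPGD (5.09) and less PTGS2 (−8.50) and MAN1C1 (−7.83), as 11 rose and 18 fell. At 6 h no gene passed for Medium by edgeR (1219 at unadjusted p under 0.05; DESeq2 221, limma-voom 0), the smallest p belonging to PLEKHF1 (1.85, adjusted p = 0.0551). In Low clones only SOX8 fell at 6 h (−3.35 ± 0.50, adjusted p = 0.0471), and it passed in 5 of 18 fits that left out 1 library. With 1 library left out the Medium count at 12 h ran from 0 without control replicate 3 to 159 without High replicate 3. The Low count ran from 0 without control replicate 1 to 128 without control replicate 4.

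Between the extreme classes, High clones at 12 h had more GNLY (4.78, adjusted p = 0.00897), IL22 (5.09, adjusted p = 0.049) and PRF1 (2.94, adjusted p = 0.0496) than Low clones and less TNF (−2.19, adjusted p = 0.0115). SERPINB2 (−10.10, adjusted p = 0.00108) and the matrix protease gene MMP10 (−7.26, adjusted p = 0.00126) were lower, and IRX3 (7.08, adjusted p = 0.00803) and EEF1A2 (7.43) higher, among 1290 genes up and 1924 down. GNLY, TNF, MMP10 and SERPINB2 passed in all 19 fits that left out 1 library, and PRF1 in 4. The lane as a covariate left 1 gene, and leaving out Low replicate 1, 2, 3 or 4 gave 5010, 2033, 2135 or 2031 genes. At 6 h 0 genes passed by edgeR (821 at unadjusted p under 0.05; DESeq2 35, limma-voom 0), and GNLY stood at 6.41 (adjusted p = 0.36).

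Along the scale from control through Low and Medium to High, HAVCR2 climbed by 1.87 per step at 6 h (adjusted p = 0.00554; 18 libraries). The fitted slopes of APBB2 (1.53), RIN3 (1.24) and NCAM1 (2.25) were positive and those of CADM1 (−2.90), HPSE (−1.55) and PHKA1 (−0.83) negative (adjusted p = 0.0442 each), among 7 genes up and 5 down. Such a slope can come from the step between control and AMTH17 alone, as for CADM1 and HPSE, and among AMTH17 libraries only edgeR called 0 genes at 6 h (717 at unadjusted p under 0.05). At 12 h the slope was 3.10 for IL22 (adjusted p = 0.0099; 19 libraries), 2.03 for GNLY (adjusted p = 0.0088), 1.58 for IL10 (adjusted p = 0.0421), 1.13 for GZMB (adjusted p = 0.0175) and 1.07 for PRF1 (adjusted p = 0.0254), among 1327 genes up and 1099 down. Of 17 cytotoxic granule genes 6 rose at 12 h and 9 when adjusted over the list alone (camera, adjusted p = 6.9e-04, adjusted p = 0.35 with an estimated correlation; fry, adjusted p = 9.7e-04). Some markers of other cells rose along the scale too. At 12 h 2 of 3 NK cell and 2 of 2 erythroid and platelet markers rose. At 6 h 0 of 8 myeloid markers passed across all genes and 7 rose when adjusted over the list alone. That list had no call at 6 h (camera, adjusted p = 0.10, adjusted p = 0.70 with an estimated correlation, fry, adjusted p = 0.46). At 12 h 0 of 9 myeloid markers passed (camera, adjusted p = 0.98). Of 12 CD4 T cell markers, which are of the clones' own cell type, 4 rose at 12 h. Of 10 TH2 genes 4 fell and 6 did not pass (camera, adjusted p = 0.0293, adjusted p = 0.79 with an estimated correlation). With lane as a covariate the trend gave 1 gene at 6 h and 0 at 12 h (1492 at unadjusted p under 0.05). With 1 library left out the count at 12 h ran from 998 without High replicate 1 to 3789 without Low replicate 1, and at 6 h from 1 to 140.

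Over all 37 libraries no change from 6 h to 12 h passed, in a fit that left the clone pairs aside. Differences between clones therefore added to its error. No gene was called out of 12441 by edgeR (209 at unadjusted p under 0.05), by DESeq2 or by limma-voom. Among genes that fell, the smallest p-values belonged to SLC3A2 (−0.36), SLC7A5 (−0.46) and CHAC1 (−0.58), none of which passed. As lists, replication-dependent histones (median −0.39; camera, adjusted p = 2.0e-07), NF-kB response (median −0.18, adjusted p = 1.5e-05), T cell activation (median −0.27, adjusted p = 1.6e-04) and interferon genes (median −0.38, adjusted p = 4.0e-04) leaned down from 6 h to 12 h. Ribosomal protein genes leaned down (median −0.06, adjusted p = 9.6e-06) and mitochondrial transcripts up (median 0.12, adjusted p = 1.5e-04, and 8.1e-05 in the 13 pairs named below). For NF-kB response, T cell activation and interferon genes the lean came from 4 of 17 clone pairs, with medians of −0.59 (NF-kB response), −0.72 (T cell activation) and −1.10 (interferon), against −0.02, 0.01 and 0.02 in the 13 others. None of the lists kept its call, the smallest being adjusted p = 0.46 with an estimated correlation. Fitted within 17 pairs of the same clone number, 1 gene passed, PCGF2, which codes for a polycomb protein (−0.75 ± 0.12, adjusted p = 0.0469), and with 1 pair left out only 1 of 17 fits called any gene. The AMTH17 effect at 12 h against 6 h differed for 0 genes by edgeR (9 at unadjusted p under 0.05; DESeq2 1, limma-voom 0).

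**Figure D3:**
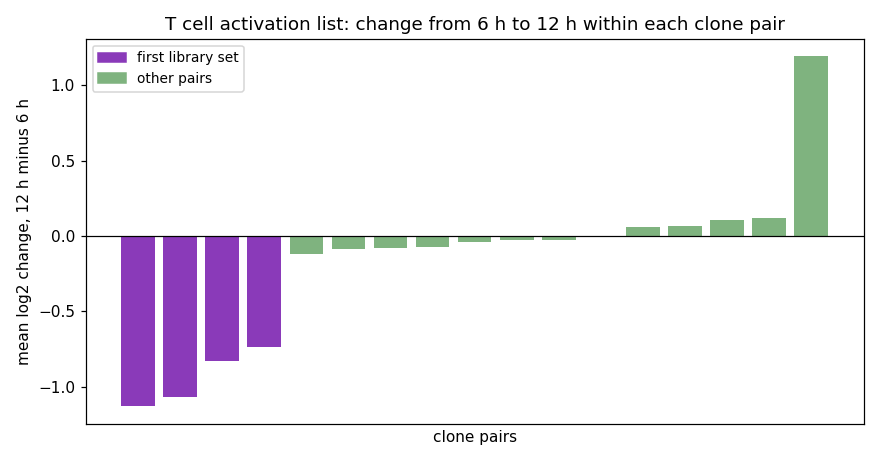
Mean change of the T cell activation genes from 6 h to 12 h in 17 clone pairs. It ran from −1.13 to −0.734 in 4 pairs and from −0.119 to 1.19 in the 13 others.

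Within each time the first principal component set 1 group of libraries apart from all others. It held 23.5% of the variance at 6 h and 32.9% at 12 h. At 12 h the set was the 6 libraries of lane 3, 5 High and 1 Low, at 71.1 to 87.6 on the component against −65.2 to 1.32 for the 13 others. At 6 h the 4 libraries with the same title numbers lay at 64.3 to 87.5, against −49.6 to 19.7 for the 14 others. These 4 shared lane 1 with 3 libraries outside the set. The values of High clones at 12 h, SERPINB2, GNLY and IL22 included, come only from libraries of this set. GNLY was high outside the set too, averaging 8.39 log2 CPM in Medium libraries at 12 h, none of which belong to it. At 6 h GNLY was at most 2.95 in Low libraries, 1 of which belongs to the set.

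**Figure D4:**
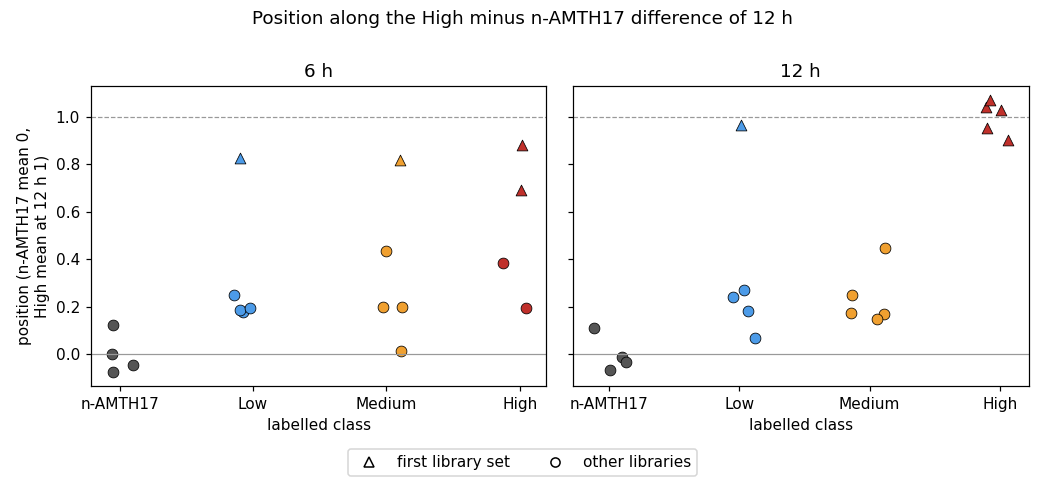
Position of each library between the mean of the controls (0) and of High clones at 12 h (1). High libraries lay at 0.902 to 1.07 at 12 h, and Low and Medium libraries of other lanes at 0.0682 to 0.446.

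**Figure D5:**
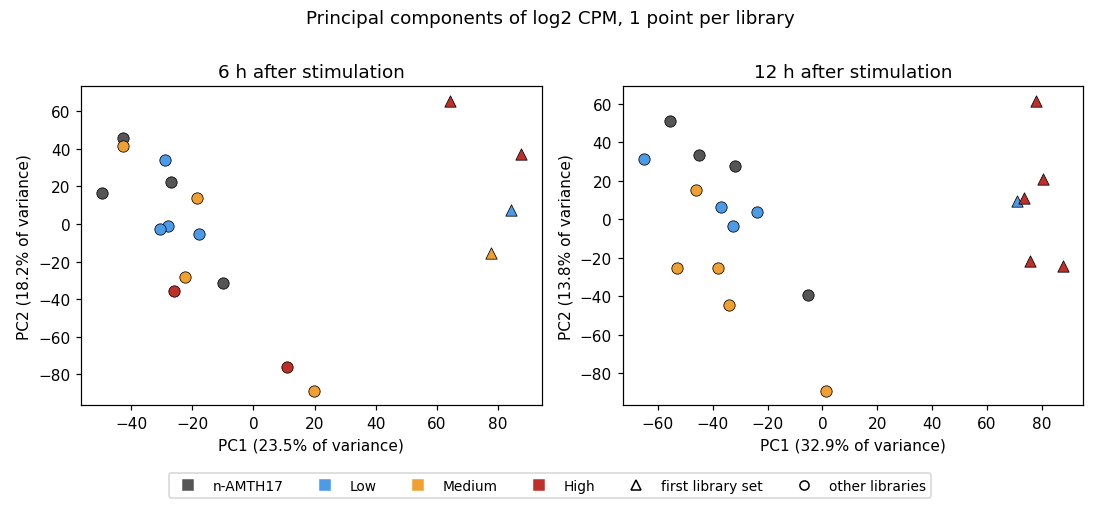
First 2 principal components at each time, libraries marked by class. The first component held 23.5% of the variance at 6 h and 32.9% at 12 h.

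The main genes lie at these GRCh38 positions, start to end: HAVCR2 on chromosome 5 (157085832 to 157142869), IL17A on chromosome 6 (52186375 to 52190638) and IL26 on chromosome 12 (68201351 to 68225821). GNLY lies on chromosome 2 (85685175 to 85698854), GZMB on chromosome 14 (24630954 to 24634267) and IL5 on chromosome 5 (132541444 to 132556838). PTGS2 (186671791 to 186680427) and PLA2G4A (186828953 to 186988981) are neighbours on chromosome 1.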

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

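The tests of sequencing lane, of a library set shared by the High clones, of antimicrobial activity and of 1 library read 2 times were chosen only after the result was seen. So was the pairing by title number, and the library set, which was first noticed in the principal components.

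Of 120 groups of 4 or 5 libraries examined for 1 library far from the others, 11 held one, where chance alone gives 1 in 20 (6 expected). Values are log2 CPM. IFNG was 13.69 in 1 High library at 6 h, against 11.18 to 11.33 in the 3 others. CCL20 was 1.83 in 1 Low and 2.18 in 1 High library at 6 h, where the others lay at 9.27 to 10.44 and 10.05 to 10.66. GNLY was 5.73 in 1 Medium library at 6 h. At 12 h PRF1 was 5.39 and TNF 11.21 in 1 High library each. In controls IL22 was 0.083 at 6 h and −0.71 at 12 h, and IL17F was 3.15 at 12 h, each in 1 library and each above the others of its group. The total count was 34300000 in 1 High library at 6 h and 14470000 in 1 High library at 12 h.

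At 12 h 4615 genes separated High clones from controls, against 2 at 6 h. By title number the High classes of the 2 times hold partly different clones. All 5 High libraries at 12 h belong to the library set, and only 2 of 4 at 6 h. The set, all AMTH17, already differed from the other libraries, controls included, at 3595 genes at 6 h, so the 2 counts alone do not show a change with time. A position was given to each library along the High minus control difference of 12 h, with controls at 0 and High clones at 1. The tables argue against the lane as the whole cause. In lane 1 at 6 h, the 4 libraries of the set and the 3 others differed in median position by 0.645 (0.693 to 0.882 against 0.00139 to 0.187). They also argue against GC content or gene length, since 3315 genes passed after a correction for both. A library set shared by the High clones stays open: its 3 libraries not labelled High had a median position of 0.824. By title number they are 1 clone labelled Low at both times (0.824 and 0.964) and 1 labelled Medium at 6 h (0.819) but High at 12 h, so only the first lies near the High clones against its label, and origin in the same donor or harvest could give this. Antimicrobial activity cannot be told apart from the set, because the only 2 High libraries outside it lay at 0.193 and 0.382 (median 0.288), and by title number both are labelled Medium at 12 h.

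1 AMTH17 library at 6 h, labelled Low, had IL26, chosen here after its values were seen, at −0.82 log2 CPM. Controls lay at −2.41 to 0.28 and other AMTH17 libraries at 1.69 to 4.49, although IL17A was at control level not only there (−0.39) but also in 1 Medium (−1.15) and 1 High (−0.36) library. Over 479 genes called at 12 h its position between controls (0) and other AMTH17 libraries (1) was 0.418, inside the control range of −0.339 to 0.46, near its upper edge, and below the 0.759 to 1.4 of the others. A mislabelled sample may therefore explain it, but the position cannot decide this. The 479 genes were called at 12 h, where this clone has no library, so a lower position may be partly built in. Every Low library at 6 h, this one included, had PTGS2 at 0.77 or less, where controls had at least 2.90. HAVCR2 was at least 3.21 in Low libraries and at most 2.80 in controls. Both genes were called with this library in the fit, and for others, such as IL5, the ranges overlapped. A clone with little TH17 expression at this time stays open and untested. Low depth is argued against, since the library holds 32.8 M counts. It has no 12 h partner by title number that could be compared.

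The change from 6 h to 12 h differed between the 4 clone pairs of the library set and the 13 other pairs at 4583 genes. Fitted apart, 1743 genes passed in the 4 pairs, and in the 13 others 0 by edgeR (2761 at unadjusted p under 0.05). Both counts depend on single pairs: leaving out 1 of the 4 gave 397 to 1017 genes, and 1 of the 13 gave 0 to 526, with calls in 4 of 13 cases. Argued against are 1 library read 2 times, as the 2 counts of the 13 pairs differed by a median chi-square per degree of freedom of 18.1 (smallest 4.72), and GC content or gene length, as 1610 genes passed in the 4 pairs after a correction. Exchanged time labels in some of the 13 pairs cannot be told apart from a true change, since T cell activation genes fell in 8 of 13, 12 changed by less than each of the 4 pairs, the other rose by 1.19 (chi-square per degree of freedom 192), as exchanged labels would give, and 2 libraries made from 1 RNA or harvest may give small changes as well.

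The groups were also compared with 100 splits of the libraries, the real one included. For AMTH17 against control at 6 h chance cannot be excluded: 8 splits gave as many as the real 20 genes, the highest other giving 214. Where the real count is 0 every split gives as many, so the splits say nothing about chance. This holds for Medium (100 splits, highest other 192) and High against Low (100, highest other 864) at 6 h, and for time and the AMTH17 effect at 12 h against 6 h (100 each, highest other 0). The splits ignore the library set, so below chance is excluded at most for libraries placed without regard to it, and chance placing of the set is not. In that sense few splits at 6 h gave as many for High (3 splits; real 2, highest other 402), Low (3; real 1, highest other 10) and the trend (3; real 12, highest other 997). The counts of 2 and 1 fall to 0 when single libraries are left out, so chance is not put aside there. At 12 h only the real split gave as many for AMTH17 (1 split, real 488, highest other 186) and High (1, real 4615, highest other 1). The same held for High against Low (1, real 3214, highest other 2228) and the trend (1, real 2426, highest other 1005). In the same sense chance is excluded there, for the full set of libraries only. With 1 library left out the lowest counts were 58 for AMTH17, 2031 for High against Low and 998 for the trend. Each lies below the highest other split. For High the lowest count was 3489. No splits were drawn with a library left out, so they cannot tell whether chance is excluded for those fits. Few splits gave as many for Medium (2, real 55, highest other 874) and Low (2, real 29, highest other 1058) at 12 h. Their counts fall to 0 without control replicate 3 (Medium) or 1 (Low), so chance is not put aside there either. At 12 h the real grouping has 5 set libraries in 1 class and the other splits at most 4. The splits with 402, 997, 874, 1058 and 2228 genes put 3 (6 h) or 4 (12 h) set libraries in 1 class. Those with 214 and 864 genes at 6 h put 2 of them in 1 class, and that with 1005 at 12 h put 3. The remaining splits with 3 at 6 h or 4 at 12 h in 1 class gave 0 genes. The placing of the set therefore does not settle where high counts arise.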

How the results depend on the processing

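The settings with the library set, the 4 pairs of differing class, GC content and length, and clone pairs as replicate block were chosen only after the result was seen. Counts are genes, and where no cause is given the cause was not tested. DESeq2 size factors changed no count by more than 1.5 times. With 1 library left out, 16355 gene results stayed the same, 178 gained a call, 765 lost it and 4 turned in sign. Signs were compared only for results called in either fit. Results called in neither fit count as the same, whatever their sign. In the self-test at the depth given, 17 of 50 genes changed 2-fold were found at 6 h, among genes with a mean CPM of at least 2.

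DESeq2 in place of edgeR gave at 6 h AMTH17 292, High 315, Medium 221, Low 68, High against Low 35 and trend 351. At 12 h it gave AMTH17 1408, Medium 542 and Low 507, and 1 for the AMTH17 effect between times. limma-voom gave AMTH17 9 and High 0 at 6 h and Medium 24 at 12 h. No low-count filter gave High 1, Low 3 and trend 25 at 6 h. A fit of 2 groups gave 48 at 12 h.

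Lane as a covariate gave at 6 h AMTH17 10, High 0, Low 0 and trend 1, and at 12 h AMTH17 0, High 0, Medium 96, Low 0, High against Low 1 and trend 0. The first library set as a covariate gave at 6 h High 0, Medium 1, Low 0 and trend 3, and at 12 h AMTH17 0, High 0, Medium 146, Low 1, High against Low 1 and trend 0. Without the first library set the counts were AMTH17 1, High 0, Medium 1, Low 0 and trend 106 at 6 h, and AMTH17 192 (120 shared), Medium 267 and trend 209 at 12 h. Without the 4 clone pairs of differing class they were AMTH17 0, High 995, Low 0, High against Low 131 and trend 29 at 6 h, and AMTH17 159, Medium 1, Low 15, High against Low 1651 and trend 1084 at 12 h. Lane 2 only gave 2 at 6 h and lane 4 only 103 at 12 h. The trend among AMTH17 libraries only gave 0 and 1494. In covariate fits lane 3 leaves the High class little to compare with, which costs calls by construction.

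With 1 library left out the counts ran at 6 h over 7 to 43 (AMTH17), 0 to 7 (High), 0 to 14 (Medium), 0 to 5 (Low), 0 to 1 (High against Low) and 1 to 140 (trend). At 12 h they ran over 58 to 1075, 3489 to 5032, 0 to 159, 0 to 128, 2031 to 5010 and 998 to 3789 in the same order. Both comparisons of times stayed at 0 to 0.

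With the clone pair as replicate block, time gave 1 gene over 17 pairs, 1743 over 4 pairs of the first library set and 0 over the 13 other pairs. Leaving out 1 pair gave 0 to 1 over the 17, 397, 524, 1010 and 1017 over the 4, and 0 over the 13 others except 195, 240, 453 and 526. The block changed no other call.

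Some named genes turned in sign. With 1 library left out, AMTH17 at 12 h had MAOA at −7.42 to 2.09, OAS1 at −3.82 to 0.45 and OAS3 at −2.65 to 0.35, above 0 only without control replicate 2. High at 12 h had IFNG at −1.18 to 4.21, the highest without control replicate 4. In the trend at 12 h, lane as a covariate gave CDC20 −0.37, GAPDH −0.0574, HSP90AA1 0.00374, DNAJA1 0.0214, LCK −0.18, CD3G −0.14 and CD3E −0.12. The first library set as a covariate gave CDC20 −0.39, GAPDH −0.0107, DNAJA1 0.00398, LCK −0.17, CD3G −0.12 and CD3E −0.10. Without that set NCF4 was −0.0469, CDC20 −0.61, LCK −0.35, CD3G −0.17 and CD3E −0.13. Among AMTH17 libraries only PTGS2 was 0.12, IL5 1.39 and GATA3 0.061. With 1 pair left out, time gave NCAM1 −3.95 over the 4 pairs and, over the 13 other pairs, CXCL8 0.31 and 0.37, LAG3 −0.28 and BCL2A1 0.34.

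Lists turned as well, given as camera adjusted p. With lane as a covariate glycolysis leaned down for AMTH17 at 12 h (0.185), and in the trend at 12 h proliferation (1.39e-08) and glycolysis (0.0141) leaned down and NF-kB response up (0.0134). For time CD4 T cell markers leaned up (0.0263). Without the first library set the 12 h trend had proliferation down (6.01e-09) and NF-kB response up (0.00828).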

Other observations

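The comparison of library sets and the fits within clone pairs were chosen only after the result was seen. In the libraries of lane 3 at 12 h and of the same title numbers at 6 h, SERPINB2 and the cytokine gene IL36G were low. Against the other libraries (4 against 14 at 6 h and 6 against 13 at 12 h), SERPINB2 changed by −11.12 and −9.92, TM4SF1 by −9.87 and −8.76, and IL36G by −6.96 and −8.05. The chemokine gene XCL2 was higher by 5.52 and 5.07. At 12 h CCL1 (5.09) and IL10 (5.04) were higher and IL6 (−6.78) lower. In all 3595 genes differed at 6 h and 6385 at 12 h, and the changes correlated at r = 0.811 over 11794 genes, where both times hold libraries of the same clones. All libraries of the set are AMTH17, while the others include every control. The changes therefore mix the set with AMTH17 status and class.

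In the 4 clone pairs of this set T cell activation genes fell from 6 h to 12 h. The genes named here were chosen after their values were seen. NR4A2 (−2.71), CD69 (−2.51), NR4A1 (−2.28), NR4A3 (−1.57), EGR2 (−1.49) and IL2 (−3.75) fell, as did the interferon-induced genes IFI44L (−7.58) and RSAD2 (−3.60). IL10 (4.56), CXCL13 (3.95), CD38 (2.61) and HLX (2.44) rose. Of 25 T cell activation genes 10 fell and 15 did not pass (camera, adjusted p = 1.6e-13, adjusted p = 0.27 with an estimated correlation), and of 20 NF-kB response genes 10 fell (camera, adjusted p = 2.3e-08, adjusted p = 0.49 with an estimated correlation). Proliferation genes leaned up (camera, adjusted p = 4.2e-06, adjusted p = 0.77 with an estimated correlation). Of 1732 genes called in the 4 pairs and tested in both, 458 (26.4%) had the same sign in the 13 other pairs.

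The 37 libraries carry 20 title numbers once the times are joined, 16 of AMTH17 and 4 of control clones, where the treatment protocol in the labels states 15 and 5 clones. 3 numbers have a library at 1 time only.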
